A study of Mus musculus with 12 samples.

How the data were processed

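The series holds 12 strand-specific, poly-dT-enriched RNA sequencing libraries of mouse peritoneal macrophages isolated by FACS, 3 from each of 4 genotypes. The labels give an age of 16 to 24 without a unit and the sex of each mouse. Genes and transcripts came from Ensembl 61 on the mm9 genome, per the file headers. The authors' processing notes name bedtools 2.16.2 and DESeq 1.6.1, and the aligner is not given in the sources used here.

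The deposited signal values are reads per gene that the authors divided by 1 size factor per library. Within each library all values (100% at a tolerance of 1e-04 reads) were whole multiples of the value of 1 read, so the reads were recovered by dividing by that value. For Samhd1 Cardif dKO replicate 2 this value was 1.00, so close to unscaled reads that the step alone cannot exclude rounding. The table holds 15721 genes, and each had at least 1 read over the 6 dKO libraries, so genes read only in WT or Samhd1 KO are missing. The deposited fold values are the ratio of the mean of Samhd1 Sting dKO to that of Samhd1 Cardif dKO, computed by the authors. The deposited log2 values are the binary logarithm of that ratio, by the authors. The deposited p-value columns give the authors' test of the same comparison and its adjusted value. These columns are used here only as the authors' deposited table.

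The plan made before the data were examined assumed raw counts with an edgeR test and named limma-trend on log2 values for files without counts. The deposited unit differed from that assumption, so limma-trend is the test reported. Values were log2(normalized reads + 1), which understates fold changes of genes with few reads. Genes with at least 10 normalized reads in at least 3 libraries were kept, 13231 in all. One linear model with a mean per group was fitted to all 12 libraries with limma 3.58.1 under R 4.3.3, with a trended prior on the variance and 8 residual degrees of freedom. Each of 6 contrasts was adjusted by Benjamini-Hochberg, with a threshold of 0.05. The median SE of a log2 fold change was 0.135. Adjusted p in the text is from limma unless another tool is named.

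On simulated data with known changes in the Samhd1 KO and WT libraries, 32.8% of genes changed by 1.5-fold, 62.7% by 2-fold and 95.5% by 4-fold were called. Of 132 calls, 5 were on unchanged genes. The shifted interferon list was called, and 0 of 15 lists without shifted genes were. The simulated genes were drawn independently of each other, so this does not check the list test where members of a list move together.

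The gene lists were fixed before the data were examined: type I interferon response genes, nucleic acid sensing and signalling genes, interferon-inducible GTPases and interferon-gamma targets, MHC class I and antigen processing, MHC class II presentation, inflammatory cytokines and NF-kB targets, p53 targets and DNA damage response, deoxynucleotide metabolism, cell cycle, large peritoneal macrophage identity, small peritoneal macrophage, monocyte and dendritic cell markers, and markers of B cells, T and NK cells, mast cells with eosinophils and basophils, neutrophils, mesothelial cells and fibroblasts, red cells and platelets, and immediate early and heat shock genes. Of 529 genes on the lists, 467 were in the table and 411 were tested, 13 of them matched by an alias or identifier. Lists were tested with camera on the log2 values at a preset correlation of 0.01, adjusted over 17 lists, and again with an estimated correlation, and with fry for the direction on balance. The mesothelial list had 2 tested genes and was not set-tested. Sex-linked genes served only as a label check. The lists are not independent of each other, since some genes stand on more than 1. The interferon score is the mean log2 value of the list's 82 tested genes per library and was compared by an exact two-sided permutation test.

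Named genes followed a rule fixed in advance. Samhd1, Mavs and Tmem173 are always named. For Samhd1 KO against WT and each dKO against Samhd1 KO, the 10 called genes with the largest rise and the 10 with the largest fall are named if their mean is at least 50 normalized reads and their groups do not overlap. The rule takes 5 each way in the other contrasts, and up to 4 members of each list by adjusted p. Where fewer passed, all that passed are named. Values of some genes that the rule takes are not reported. Left out were Xist, Y-linked genes, immunoglobulin segments and gene models without a symbol, unless on a list. For each gene named by size of change, all 3 libraries of one group lay above all 3 of the other.

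The split of the response was compared with 50 simulations in which both dKO groups were drawn like Samhd1 KO while sharing its libraries. Each contrast shares the libraries of a group with other contrasts, and 3 libraries cannot be divided between them. Alternatives were edgeR 4.0.16 with TMM or DESeq2 size factors, DESeq2 1.42.0, limma-voom, other filters, pseudocounts of 0.5 and 5, a threshold of 0.10, the 2 groups alone, covariates for sex and age, a block on the replicate number, and leaving out each library. The edgeR test with TMM was the plan's main test for raw counts, and its use on the recovered reads was added after the data were seen. TMM factors in limma and covariates for the B cell and cell cycle scores were also added then.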

Results

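Messenger RNA was sequenced from mouse peritoneal macrophages sorted by FACS. The 12 libraries fell into 4 genotype groups of 3: WT, Samhd1 KO, Samhd1 Cardif dKO and Samhd1 Sting dKO. SAMHD1 is an enzyme that breaks down deoxynucleotides, Cardif is another name of MAVS, the adaptor of the RNA sensors RIG-I and MDA5, and STING is the adaptor of the DNA sensor cGAS. Recovered depth was 24904329, 24311188 and 32204657 reads in WT and 28675866, 21953731 and 24251387 in Samhd1 KO. It was 22345221, 23103719 and 18884021 reads in Samhd1 Cardif dKO and 21000618, 20702274 and 19294490 in Samhd1 Sting dKO. Between 15238 and 15470 genes had a read in each library, and the 10 most abundant genes took 13.4% to 16.7% of the reads. Lyz2 or Fn1, both abundant in macrophages, was the top gene in every library. All libraries came from female mice except Samhd1 Cardif dKO replicate 1, and Xist (59.4 normalized reads against 7990 to 14458 in the others) and Ddx3y (1903 against at most 3.30) matched these labels. The labelled age was 16 in every WT library and 19, 18 and 16 in Samhd1 KO. It was 18, 18 and 16 in Samhd1 Cardif dKO and 24, 16 and 18 in Samhd1 Sting dKO. Age was thus not balanced against WT in any contrast with WT, and is partly mixed with genotype there. Levels below are normalized reads, given as mean ± SD with n = 3 per group, and fold changes are log2 values with their standard error (SE).

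The genes named by the genotypes were read first. Samhd1 (ENSMUSG00000027639) fell from 10761 ± 713 in WT to 6520 ± 1167 in Samhd1 KO, a log2 change of -0.74 (SE 0.167, adjusted p = 0.0305), and stood at 3613 ± 678 in Samhd1 Cardif dKO and 3683 ± 763 in Samhd1 Sting dKO. Against WT the log2 change was -1.59 (adjusted p = 0.00186) and -1.56 (adjusted p = 0.000877) in these 2 groups, so that transcript of the gene was still read in every Samhd1-deficient library. Mavs (ENSMUSG00000037523) was at 518 ± 8.05 in Samhd1 Cardif dKO and 910 ± 64.1 in Samhd1 KO, a log2 change of -0.81 (SE 0.101, adjusted p = 0.0172), and at 859 ± 47.9 in WT and 911 ± 126 in Samhd1 Sting dKO. Tmem173 (ENSMUSG00000024349), which encodes STING, was at 551 ± 22.4 in Samhd1 Sting dKO, 735 ± 36.6 in Samhd1 KO, 614 ± 38.3 in Samhd1 Cardif dKO and 522 ± 36.0 in WT. It fell in Samhd1 Sting dKO against Samhd1 KO (log2 -0.41, SE 0.084, adjusted p = 0.0149), but against WT its log2 change was 0.08 (adjusted p = 0.622). The gene-level reads therefore do not check the Sting label, and the libraries labelled Samhd1 Sting dKO are described by that label. Samhd1 in Samhd1 KO was no longer past the threshold without any one of WT replicates 1, 2 and 3 or Samhd1 KO replicates 1 and 3 (log2 -0.69, -0.78, -0.74, -0.71 and -0.63). The same held for Mavs without Samhd1 KO replicate 1 or 2 or Samhd1 Cardif dKO replicate 1, 2 or 3 (log2 -0.77, -0.87, -0.80, -0.82 and -0.81), and for Tmem173 in Samhd1 Sting dKO against Samhd1 KO without Samhd1 KO replicate 2 (-0.38) or Samhd1 Sting dKO replicate 2 (-0.40).

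**Figure D1:**
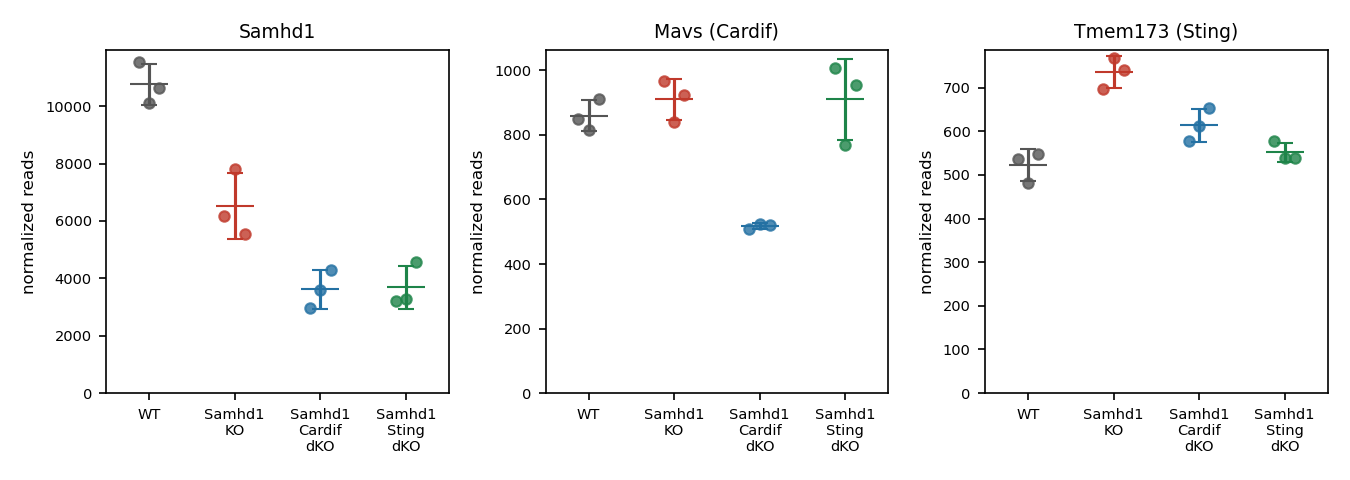
Normalized reads of Samhd1, Mavs and Tmem173 (vertical axes, linear, from 0) in the 4 groups (horizontal axes). Each point is a library, and the bar and whiskers are the mean and SD of 3 libraries. Mavs was at 518 in Samhd1 Cardif dKO and at 859 to 911 in the other groups, while Tmem173 in Samhd1 Sting dKO (551) lay near the WT level (522).

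The comparison of Samhd1 KO with WT asks what loss of SAMHD1 changes in these macrophages. Genes of the type I interferon response rose together: 54 of the 82 tested genes of that list were higher by limma, 0 were lower by limma, edgeR or DESeq2, and 69 were higher when adjusted over the list alone. Their median log2 change was 0.80 (camera adjusted p = 1.99e-42, and adjusted p = 0.104 with an estimated correlation; fry adjusted p = 0.00304). Ifi44 (ENSMUSG00000028037) rose from 12.6 ± 4.42 to 275 ± 94.5 normalized reads (log2 4.33, SE 0.494, adjusted p = 0.00259). Oas3, which makes the activator of RNase L, rose from 725 ± 238 to 2622 ± 59.2 (log2 1.91, SE 0.240), Oasl1 by log2 2.69 (SE 0.372), Ifit3 by 2.09 (SE 0.396), Ifi205 by 2.44 (SE 0.515), Znfx1 by 0.87 (SE 0.0926) and Lgals3bp by 0.81 (SE 0.0941). The mean of the list per library was 10.4 ± 0.107 in Samhd1 KO and 9.52 ± 0.247 in WT, a difference of 0.90 on the log2 scale. All 3 Samhd1 KO libraries lay above all 3 WT libraries (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows).

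Other interferon-related groups moved the same way in Samhd1 KO. Of 35 nucleic acid sensing and signalling genes, 9 were higher (10 adjusted over the list alone, median 0.15, camera adjusted p = 1.54e-05, and adjusted p = 0.104 with an estimated correlation). Among them were Irf7, the transcription factor that amplifies interferon production (log2 1.74, SE 0.230), Zbp1 (1.36), Ddx58, which encodes RIG-I (0.80), and Tmem173 (0.49). Of the 35 genes, 8 also stand on another list. Irf7, Zbp1 and Ddx58 are on the type I interferon list as well, so the 2 lists are not separate evidence. Of 23 interferon-inducible GTPases and interferon-gamma targets, 10 were higher (18 by DESeq2, 19 adjusted over the list alone, median 1.08, camera adjusted p = 1.75e-14, and adjusted p = 0.146 with an estimated correlation). Gbp4 (log2 2.70), Gbp8 (2.61), Tgtp2 (2.25) and Iigp1 (2.23) had the largest rises there, and Gbp6 (1.56), Ifi47 (1.35) and Gbp9 (1.23) were also higher. Samhd1 KO replicate 2 stood apart in this group, with Iigp1 at 3806.9 against 1225 and 872 in replicates 1 and 3 (mean 1968 ± 1602), Gbp4 at 431 against 94.0 and 52.8 (193 ± 208), and a list score of 9.89 against 8.75 and 8.63. Of 22 genes of MHC class I and antigen processing, 7 were higher (12 by DESeq2, 16 adjusted over the list alone, median 0.43, camera adjusted p = 1.75e-14, and adjusted p = 0.146 with an estimated correlation). These included H2-Q6 (1.59), H2-Q7 (1.45), H2-Q4 (0.98, listed as H2-gs10) and Nlrc5, the activator of class I genes (0.98, listed as AI451557). Of 11 MHC class II genes, 4 were higher: Cd74 (1.27), H2-Eb1 (1.21), H2-Ab1 (1.18) and H2-Aa (1.13). Adjusted over the list alone, 7 were higher and 1 lower (median 0.44, camera adjusted p = 0.00363, and adjusted p = 0.298 with an estimated correlation). Samhd1 KO replicate 2 was highest in both MHC lists. Its score was 12.08 against 11.66 and 11.69 in replicates 1 and 3 for class I, and 10.04 against 9.66 and 9.40 for class II. Of 29 inflammatory and NF-kB target genes, 5 were higher (6 adjusted over the list alone, median 0.39, camera adjusted p = 3.35e-05, and adjusted p = 0.146 with an estimated correlation). These included Bcl3 (1.25), the adhesion molecule Icam1 (1.04), Tnfaip2 (0.87) and the costimulatory receptor Cd40 (0.62). Outside these lists, the receptor tyrosine kinase Axl rose from 635 ± 187 to 3203 ± 378 (log2 2.37, SE 0.288) and the sialic acid-binding receptor Siglec1 from 1349 ± 436 to 5126 ± 782 (log2 1.97, SE 0.404).

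Among the genes that fell in Samhd1 KO was the heat shock gene Hspa1b, from 208 ± 83.1 to 45.1 ± 9.86 (log2 -2.13, SE 0.326, adjusted p = 0.00643). Rgs1 (-1.87), Clec4g (-1.85), Zfp9 (-1.84), the actin-bundling gene Fscn1 (-1.73), Slc10a6 (-1.57), the cell cycle inhibitor locus Cdkn2a (-1.54), Hspa1a (-1.39), the oxysterol receptor Gpr183 (-1.33) and Tmtc2 (-1.31) were also lower. Of the 26 immediate early and heat shock genes, 6 were lower and 2 higher (1 higher by edgeR and 4 by DESeq2; 8 and 6 adjusted over the list alone), and the lower ones included Hsph1 (-1.30), Hspa8 (-0.67) and Dnaja1 (-0.67). The list's median was 0.07 and its mean -0.08 (camera adjusted p = 0.239, direction down). In deoxynucleotide metabolism, 2 of 23 genes were higher, the interferon-induced kinase gene Cmpk2 (1.14) and the deoxycytidine kinase gene Dck (0.91), and 1 was lower, Samhd1 itself (3 higher and 1 lower adjusted over the list alone, median -0.03, mean 0.23, camera adjusted p = 0.683, direction up). Of 29 p53 targets, 1 was lower, Plk3 (-0.75), with 2 lower by DESeq2 and 1 adjusted over the list alone (median -0.07, camera adjusted p = 0.251). Phlda3 was at log2 -1.03, Dcxr at -0.37 and Tigar at 0.37 (listed as 9630033F20Rik), all 3 short of the threshold.

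Cell identity markers were also read in this comparison. Of 32 large peritoneal macrophage genes, 1 was higher, Bhlhe40 (log2 0.77), with 2 lower by DESeq2, and 1 higher and 1 lower adjusted over the list alone (median -0.09, camera adjusted p = 0.251). Vsig4 (-0.72), Thbs1 (-0.69) and Ltbp1 (-0.39) did not pass. Of 22 markers of small peritoneal macrophages, monocytes and dendritic cells, 3 were higher, among them Zbtb46 (1.08) and the Fc receptor Fcgr4 (1.06), and 1 was lower, Cd209a (-1.28). DESeq2 called 6 higher. Adjusted over that list alone, 8 were higher and 3 lower (median 0.67, camera adjusted p = 0.00261, and adjusted p = 0.104 with an estimated correlation). The median of B cell markers in Samhd1 KO against WT was -1.01, 0 of 21 were called by limma or edgeR, 12 were lower at an unadjusted p under 0.05 and 4 by DESeq2, and 10 were lower adjusted over the list alone (camera adjusted p = 3.70e-07, and adjusted p = 0.292 with an estimated correlation). Cd79a was at log2 -1.36, Blk at -1.35 and Ebf1 at -1.02. Of 10 mast cell, eosinophil and basophil markers, 3 mast cell protease genes were lower, Cma1 (-4.33), Tpsb2 (-3.51) and Mcpt4 (-3.39), with 1 lower by edgeR and 5 adjusted over the list alone (median -1.56, camera adjusted p = 0.000635, and adjusted p = 0.146 with an estimated correlation). Cma1 was at 46.7 ± 25.8 in WT and 1.49 ± 1.42 in Samhd1 KO, close to the floor. All 37 cell cycle genes had a positive log2 change (median 1.15, camera adjusted p = 3.35e-05, and adjusted p = 0.489 with an estimated correlation), but 0 were called by limma, edgeR or DESeq2 and 0 were under an unadjusted p of 0.05. The cell cycle score ran from 7.42 to 9.40 in Samhd1 KO and from 6.32 to 8.84 in WT. Mki67, for example, was at 2565 ± 1456 and 1068 ± 874. Of 9 neutrophil markers, Prtn3 was higher (0.70; edgeR called 0 and DESeq2 2), with a list median of 0.62 (camera adjusted p = 0.207). Of 4 red cell and platelet markers, Pf4 was lower (-0.56), with a list median of -0.22 (camera adjusted p = 0.207). The 6 T and NK cell markers had a median of -0.43 (camera adjusted p = 0.127), and 0 of them were called by limma, edgeR or DESeq2 or were under an unadjusted p of 0.05. Of the mesothelial and fibroblast list only Krt7 (-0.46) and Cav1 (-0.39) were tested, and neither passed.

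Over all 13231 tested genes, limma called 358 higher and 214 lower in Samhd1 KO than in WT, 137 of them changed by over 2-fold, and 2487 were under an unadjusted p of 0.05. The count of 572 fell to 289, 273 and 185 without WT replicate 1, 2 or 3, and to 248 and 277 without Samhd1 KO replicate 2 or 3. The count of 54 interferon genes fell to 31, 31, 27 and 34 without WT replicate 2 or 3 or Samhd1 KO replicate 2 or 3. DESeq2 called 1056 genes, and with the B cell marker score as a covariate 124 were called.

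The comparison of Samhd1 Cardif dKO with Samhd1 KO asks what removing MAVS changes in cells without SAMHD1. Interferon-related genes fell. Limma called 19 genes lower and 0 higher, and 6 of the 82 type I interferon response genes were among the lower ones. Falls were seen in the GTPase gene Gbp8, from 165 ± 93.4 to 21.6 ± 7.62 (log2 -2.79, SE 0.387, adjusted p = 0.0240), and in Serpina3g (-2.17, SE 0.362). Irf7 fell from 5252 ± 843 to 1824 ± 390 (-1.53, SE 0.230) and Lgals3bp from 30631 ± 671 to 17988 ± 1623 (-0.77, SE 0.0941). Gbp6 (-1.50), H2-Q6 (-1.29), Gvin1 (-1.03), Thbs3 (-0.88), Mavs (-0.81), Herc6 (-0.68) and Trim30a (-0.48) were also lower.

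As a group, all 82 interferon genes had a negative log2 change in Samhd1 Cardif dKO against Samhd1 KO (median -0.67). Adjusted over the list alone, 69 were lower, and camera gave an adjusted p of 1.02e-62 and an adjusted p of 0.0416 with an estimated correlation. The list's mean per library was 9.66 ± 0.233 against 10.4 ± 0.107, a difference of -0.76, with no overlap between the groups (exact permutation test, two-sided p = 0.1, the smallest possible). Of the 35 sensing genes, 2 were lower, Mavs and Irf7 (1 by edgeR, 6 by DESeq2, 10 adjusted over the list alone, median -0.12, camera adjusted p = 6.17e-10, and adjusted p = 0.0416 with an estimated correlation). Ddx58 and Ifih1, which encodes MDA5, were both at -0.67 with adjusted p = 0.0560 and 0.0566. Irf7, Ddx58 and Ifih1 are also on the type I interferon list. Of the 23 GTPases and interferon-gamma targets, 4 were lower (17 by DESeq2, 19 adjusted over the list alone, median -1.14, camera adjusted p = 7.86e-26, and adjusted p = 0.0780 with an estimated correlation). Of the 22 MHC class I genes, 1 was lower (11 by DESeq2, 17 adjusted over the list alone, median -0.47, camera adjusted p = 1.29e-21, and adjusted p = 0.0780 with an estimated correlation). Limma and edgeR called 0 of 11 MHC class II genes and 0 of 29 inflammatory genes. At an unadjusted p under 0.05, 5 and 11 were lower, and DESeq2 called 3 of each. Their medians were -0.21 (camera adjusted p = 0.00356, and adjusted p = 0.315 with an estimated correlation) and -0.38 (camera adjusted p = 9.37e-08, and adjusted p = 0.0794 with an estimated correlation). In the same contrast, B cell markers had a median of 0.51 (camera adjusted p = 0.000385, and adjusted p = 0.357 with an estimated correlation), and 0 of 21 were called by limma, edgeR or DESeq2 or were under an unadjusted p of 0.05. Mast cell, eosinophil and basophil markers had a median of 0.44 (camera adjusted p = 0.0442, and adjusted p = 0.315 with an estimated correlation). Cell cycle genes had a median of 0.24 (camera adjusted p = 0.0477, and adjusted p = 0.715 with an estimated correlation). For small macrophage, monocyte and dendritic cell markers it was -0.16 (camera adjusted p = 0.0126, and adjusted p = 0.0925 with an estimated correlation), and for immediate early and heat shock genes -0.21 (camera adjusted p = 0.00356, and adjusted p = 0.315 with an estimated correlation).

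The gene count of this comparison depended on single libraries and on the tool. Without Samhd1 KO replicate 2 or any one of Samhd1 Cardif dKO replicates 1, 2 and 3 it was 0, without Samhd1 KO replicate 1 it was 1, without WT replicates 1, 2 and 3 it was 12, 31 and 7, and without Samhd1 Sting dKO replicate 2 or 3 it was 9. The 6 interferon genes became 3, 15 and 1 without WT replicate 1, 2 or 3, 0 without Samhd1 KO replicate 1 or 2 or any one Samhd1 Cardif dKO library, and 2 and 1 without Samhd1 Sting dKO replicate 2 or 3. The 6 also became 3 with a filter at 5 CPM or TMM factors, 0 from the 2 groups alone or with sex as a covariate, 1 with age, 25 with the B cell score, 27 with the cell cycle score and 47 by DESeq2. The gene count was 0 with sex as a covariate, 6 with age, 49 with the B cell score, 66 with the cell cycle score, 11 with a filter at 5 CPM and 1 from the 2 groups alone. DESeq2 called 17 genes higher and 169 lower, edgeR 0 higher and 17 lower, and 1188 genes were under an unadjusted p of 0.05.

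The comparison of the libraries labelled Samhd1 Sting dKO with Samhd1 KO asks what removing STING changes in cells without SAMHD1. Interferon response genes fell here in large number: 68 of 82 were lower by limma, 0 were higher by limma, edgeR or DESeq2, and 75 were lower adjusted over the list alone (median -1.08, camera adjusted p = 1.42e-61, and adjusted p = 0.0876 with an estimated correlation). Ifi44 fell from 275 ± 94.5 to 6.49 ± 4.0 (log2 -5.31, SE 0.494, adjusted p = 0.000220), Oasl1 from 220 ± 17.5 to 13.8 ± 4.0 (-3.94, SE 0.372), Ifi205 by -3.42 on the log2 scale, Ifit1 by -2.91, the antiviral gene Rsad2 by -2.80, Oas3 by -2.78 and Ifi27l2a by -2.76. Lgals3bp (-1.48), Herc6 (-1.29) and Trim30a (-0.96) fell as well. The list's mean per library was 9.10 ± 0.0794 against 10.4 ± 0.107, a difference of -1.31 with no overlap (exact permutation test, two-sided p = 0.1, the smallest possible).

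Related groups fell with it in the libraries labelled Samhd1 Sting dKO. Of 23 GTPases and interferon-gamma targets, 15 were lower (19 adjusted over the list alone, median -1.34, camera adjusted p = 3.64e-16, and adjusted p = 0.131 with an estimated correlation). Gbp8 was at log2 -4.14, Iigp1 at -3.59, Tgtp2 at -2.92, Gbp6 at -2.31, Gbp9 at -1.76 and Gvin1 at -1.34. Of 22 MHC class I genes, 15 were lower (19 adjusted over the list alone, median -0.69, camera adjusted p = 1.18e-18, and adjusted p = 0.0980 with an estimated correlation). H2-Q7 was at -1.85, H2-Q6 at -1.81, Nlrc5 at -1.30 (listed as AI451557) and H2-Q4 at -1.01 (listed as H2-gs10). Of 35 sensing genes, 10 were lower and 1 higher (12 and 1 adjusted over the list alone, median -0.17, camera adjusted p = 1.48e-06, and adjusted p = 0.0980 with an estimated correlation). These included Irf7 (-2.21), Dhx58 (-0.97), Ddx58 (-0.93) and the RNA-editing gene Adar (-0.79), all of them also on the type I interferon list. Of 29 inflammatory genes, 3 were lower, Cxcl1 (-0.86), Cxcl2 (-0.83) and Icam1 (-0.77), with 5 lower and 1 higher by DESeq2 and 4 lower adjusted over the list alone (median -0.17, camera adjusted p = 0.0217, and adjusted p = 0.418 with an estimated correlation). Of 23 deoxynucleotide genes, 4 were lower, Dck (-1.42), Cmpk2 (-1.31), the purine phosphorylase gene Pnp (-0.85) and Samhd1 (-0.83), also 4 adjusted over the list alone (median -0.10, camera adjusted p = 0.00795, and adjusted p = 0.370 with an estimated correlation). Of 11 MHC class II genes, 3 were higher, H2-Oa (1.90), H2-DMb2 (1.54) and H2-Ob (1.04), whose products act in class II peptide loading in B cells among others. By DESeq2 1 was lower. Adjusted over that list alone, 3 were higher and 1 lower (median -0.18, mean 0.23, camera adjusted p = 0.868, direction up).

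Markers of other cells also differed in the libraries labelled Samhd1 Sting dKO. B cell markers were higher: 16 of 21 rose, and 20 rose adjusted over the list alone (median 2.47, camera adjusted p = 1.72e-20, and adjusted p = 0.0980 with an estimated correlation). Igh-6, the immunoglobulin mu chain, rose from 327 ± 96.3 to 1964 ± 768 (log2 2.54, SE 0.349, adjusted p = 0.00198), and Cd79b (2.56), Cd22 (2.64), Ebf1 (2.63), Cd79a (2.59), Igk-C (2.74) and Igl-C2 (2.53) rose by similar amounts. Other genes that rose were Ly6d (2.81), Siglecg (2.57), Gimap4 (2.53) and, largest of all named genes, the retinaldehyde dehydrogenase gene Aldh1a3 (ENSMUSG00000015134), from 2.42 ± 0.768 to 824 ± 420 (log2 7.83, SE 0.412, adjusted p = 3.45e-06). Of 10 mast cell, eosinophil and basophil markers, 5 were higher, among them Cma1 (4.69), Mcpt4 (4.48), Tpsb2 (3.90) and Il5ra (1.96), with 6 higher adjusted over the list alone (median 2.35, camera adjusted p = 0.000651, and adjusted p = 0.135 with an estimated correlation). Replicates 1 and 2 carried most of this rise: Cma1 was at 96.8, 138 and 11.9 in replicates 1, 2 and 3, Mcpt4 at 78.1, 107 and 8.35 and Tpsb2 at 74.8, 133 and 5.96, and the list score at 5.84, 6.00 and 4.11, against 3.08 to 3.35 in Samhd1 KO. Against WT this list score differed by 0.42 with overlapping groups (exact permutation test, two-sided p = 0.6). There edgeR and DESeq2 called 0 of the markers, and 1 was higher at an unadjusted p under 0.05. Of 6 T and NK cell markers, limma called 0, edgeR and DESeq2 each called 1 higher, 4 were higher at an unadjusted p under 0.05 and 1 adjusted over the list alone (median 1.22, camera adjusted p = 0.00246, and adjusted p = 0.0980 with an estimated correlation). Cell cycle genes had a median of -2.12, with 0 of 37 called by limma or edgeR, 28 lower at an unadjusted p under 0.05, 13 lower by DESeq2 and 27 lower adjusted over the list alone (camera adjusted p = 6.07e-13, and adjusted p = 0.369 with an estimated correlation). Among 32 large macrophage genes, F10 (-0.74) and Cd5l (-0.64) were lower (median -0.06, camera adjusted p = 0.528). Of 22 small macrophage, monocyte and dendritic cell markers, 2 were lower, among them Fcgr4 (-1.60), while limma called 0 higher, edgeR 1 and DESeq2 2 (median 0.01, mean -0.03, camera adjusted p = 0.627).

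The libraries labelled Samhd1 Sting dKO had 366 genes higher and 383 lower than Samhd1 KO by limma, and 280 of them changed by over 2-fold. The count of 749 fell to 421 and 467 without Samhd1 KO replicate 2 or 3, to 422 without Samhd1 Sting dKO replicate 2, to 461 from the 2 groups alone, and to 241 with the cell cycle score as a covariate, and it rose to 1284 by DESeq2. With the B cell score as a covariate, 33 genes were called, of which 21 were interferon genes, and Ly6d (-0.0578), Igk-C (-0.12), Cd79a (-0.10), Igl-C2 (-0.52), H2-DMb2 (-0.20) and Il5ra (-0.87) changed sign.

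**Figure D2:**
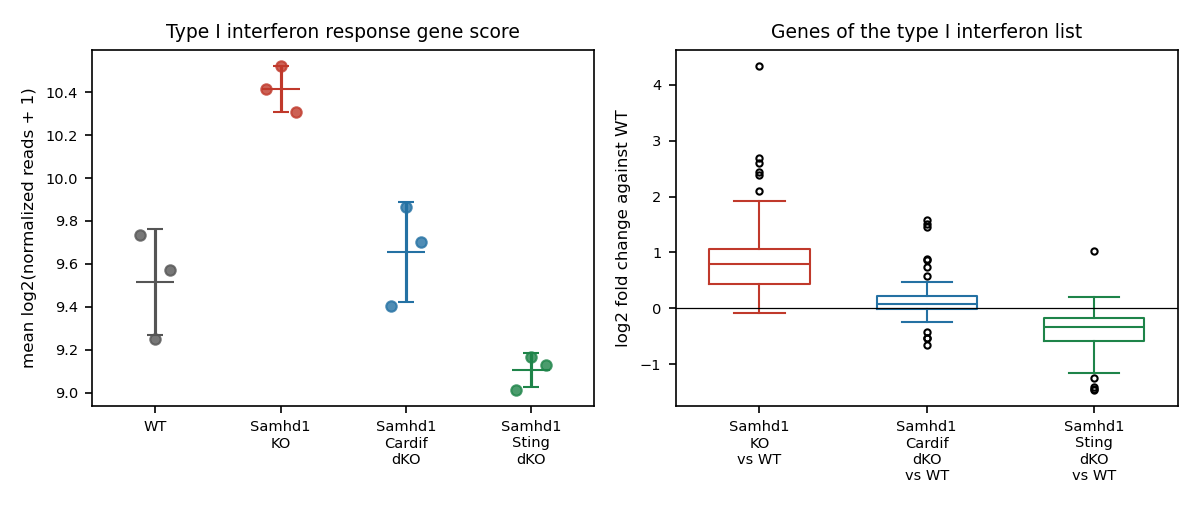
The first panel gives the mean of log2(normalized reads + 1) over the 82 type I interferon response genes for each library (points), with the mean and SD of 3 libraries per group (bars and whiskers); the axis does not start at 0. The second panel gives the log2 fold change of each gene of the list against WT as box plots (median, quartiles, whiskers to 1.5 times the quartile range). The score was 10.4 in Samhd1 KO, 9.52 in WT, 9.66 in Samhd1 Cardif dKO and 9.10 in Samhd1 Sting dKO, and the medians were 0.80, 0.07 and -0.34.

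Of the 358 genes higher in Samhd1 KO than in WT, 17 were called lower in Samhd1 Cardif dKO and 151 (42.2%) in the libraries labelled Samhd1 Sting dKO. Simulated dKO groups drawn like Samhd1 KO, which share the same Samhd1 KO libraries, gave a mean of 0.06 and 0.04 such genes and at most 1 in 50 simulations. The simulations drew the noise of each gene on its own. They leave out shifts that many genes of a library share, and so may understate such counts. By sign alone 334 and 295 of the 358 were lower, where the simulations gave 170.5 and 170.0 of a mean of 299 genes. The median log2 change of the 358 genes was 0.69 in Samhd1 KO, 0.30 in Samhd1 Cardif dKO and 0.26 in Samhd1 Sting dKO, each against WT, and 40 and 110 of them were still called above WT in the 2 dKO groups. The same simulations gave a mean of 260.4 and 261.8 such genes. Independent lists would give 1.24 and 12.8, which leaves out the shared WT libraries. The simulations took the fitted changes of genes called in Samhd1 KO as true, and choosing genes by their calls tends to overstate changes. The means of 260.4 and 261.8 may therefore be too high. Part of the fall of the median from 0.69 to 0.30 and 0.26 may come from the same choice. Lower in both dKO groups than in Samhd1 KO were 16 genes. Independent lists would share 0.550, which leaves out the shared Samhd1 KO libraries, and the simulations gave a mean of 0.02, which leaves out the effects. Neither tests the overlap, and how much of it came from the shared libraries is not known. The 17 became 9, 4, 1 and 0 without WT replicate 1 or 3 or Samhd1 KO replicate 1 or 2, 0 without any one Samhd1 Cardif dKO library, and 10, 8 and 8 without Samhd1 Sting dKO replicate 1, 2 or 3. The 151 became 96, 78 and 65 without WT replicate 1, 2 or 3 and 99, 59 and 99 without Samhd1 KO replicate 1, 2 or 3. Under other settings the 17 became 134 by DESeq2, 9 with a filter at 5 CPM, 1 from the 2 groups alone, 0 with sex, 4 with age, 43 with the B cell score and 52 with the cell cycle score as a covariate. The 151 became 242 by DESeq2, 100 with age and 31 with the B cell score as a covariate.

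The comparison of Samhd1 Cardif dKO with WT asks what was left of the response without MAVS. Limma and edgeR called 0 of 82 type I interferon response genes, 11 were higher and 2 lower at an unadjusted p under 0.05, DESeq2 called 3 higher, and limma called 1 higher without Samhd1 Sting dKO replicate 3. Their median was 0.07 (camera adjusted p = 0.0503), and the score differed by 0.14 with overlapping groups (exact permutation test, two-sided p = 0.6). The actin regulator gene Coro1a rose from 562 ± 27.9 to 2854 ± 824 (log2 2.30, SE 0.441, adjusted p = 0.0325), with the growth factor gene Pdgfb (1.72), Cass4 (1.42), Skint3 (1.39) and Clec2g (1.32) also higher. Hspa1b fell from 208 ± 83.1 to 41.8 ± 6.61 (-2.23, SE 0.326, adjusted p = 0.00879), and the clock gene Per1 (-2.00), Hspa1a (-1.79), Zbtb16 (-1.73) and Tsc22d3 (-1.71) were also lower. Of 26 immediate early and heat shock genes, limma called 6 lower and 0 higher and DESeq2 7 lower and 3 higher (9 lower and 3 higher adjusted over the list alone, median -0.25, camera adjusted p = 0.00511, and adjusted p = 0.716 with an estimated correlation). Cell cycle genes had a median of 1.42 (camera adjusted p = 2.22e-09, and adjusted p = 0.716 with an estimated correlation). EdgeR and DESeq2 called 0 of them, and 5 were higher at an unadjusted p under 0.05. Their scores overlapped, at 10.16, 8.02 and 8.72 in Samhd1 Cardif dKO replicates 1 (the male), 2 and 3 against 6.32 to 8.84 in WT. B cell markers had a median of -0.48 (camera adjusted p = 0.0118, and adjusted p = 0.787 with an estimated correlation). For mast cell, eosinophil and basophil markers it was -1.04 (camera adjusted p = 0.0358, and adjusted p = 0.716 with an estimated correlation) and for p53 targets -0.15 (camera adjusted p = 0.0187, and adjusted p = 0.716 with an estimated correlation). Limma called 46 genes higher and 94 lower. The 140 became 49, 46 and 37 without WT replicate 1, 2 or 3, 42, 65 and 85 without Samhd1 Cardif dKO replicate 1, 2 or 3, 67 from the 2 groups alone, 42 with sex, 48 with the B cell score and 59 with the cell cycle score as a covariate, and 475 by DESeq2.

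The comparison of the libraries labelled Samhd1 Sting dKO with WT asks what was left of the response without STING. Part of the interferon list was below WT: 13 of 82 genes were called lower, and 22 were lower adjusted over the list alone (median -0.34, camera adjusted p = 2.44e-12, and adjusted p = 0.457 with an estimated correlation). At an unadjusted p under 0.05, 36 were lower and 2 higher. The score differed by -0.41 with no overlap (exact permutation test, two-sided p = 0.1, the smallest possible). Aldh1a3 rose by log2 7.57 (SE 0.412, adjusted p = 5.05e-06), the clock output gene Dbp from 25.1 ± 13.6 to 291 ± 23.3 (3.60, SE 0.437), the clock repressor gene Nr1d1 by 3.14, Rprm by 2.31 and Pdgfb by 2.11. Fkbp5, a glucocorticoid-responsive gene, fell from 6455 ± 575 to 675 ± 651 (-3.68, SE 0.656, adjusted p = 0.00856), and Zbtb16 (-2.33), Tdo2 (-2.32), Wee1 (-2.01) and Hsph1 (-1.92) were lower. B cell markers rose in 8 of 21 cases (15 by DESeq2, 16 higher adjusted over the list alone, median 1.42, camera adjusted p = 5.73e-10, and adjusted p = 0.457 with an estimated correlation). Of 11 MHC class II genes, 3 were higher (6 by DESeq2, 8 higher and 1 lower adjusted over the list alone, median 0.88, camera adjusted p = 0.000597, and adjusted p = 0.457 with an estimated correlation). Medians of the other lists that passed were -0.99 for cell cycle genes (camera adjusted p = 0.000597, and adjusted p = 0.647 with an estimated correlation) and -0.13 for MHC class I (camera adjusted p = 0.0127, and adjusted p = 0.647 with an estimated correlation). Deoxynucleotide metabolism was at -0.23 (camera adjusted p = 0.0174, and adjusted p = 0.457 with an estimated correlation) and GTPases and interferon-gamma targets at -0.31 (camera adjusted p = 0.0347, and adjusted p = 0.665 with an estimated correlation). Limma called 472 genes higher and 388 lower. The 860 became 358, 423 and 361 without WT replicate 1, 2 or 3, 535 and 454 without Samhd1 Sting dKO replicate 2 or 3, 423 with age and 140 with the B cell score as a covariate, and 1391 by DESeq2. The 13 interferon genes became 7, 21 and 7 without WT replicate 1, 2 or 3, 7 and 8 without Samhd1 Sting dKO replicate 1 or 3, 6 with age, 8 with the B cell score and 24 with the cell cycle score as a covariate, and 21 by DESeq2.

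The direct comparison of both dKO groups asks whether the second knockouts differ in their effect. Interferon response genes were higher in Samhd1 Cardif dKO than in the libraries labelled Samhd1 Sting dKO: 9 of 82 were higher, with 1 lower by DESeq2 and 42 higher and 1 lower adjusted over the list alone (median 0.40, camera adjusted p = 2.10e-25, and adjusted p = 0.235 with an estimated correlation). Oasl1 (log2 2.13, SE 0.372), Ifi27l2b (1.61, SE 0.255), Ifi27l2a (1.59, SE 0.253), Oas3 (1.44, SE 0.240) and Usp18, a brake on interferon signalling (1.43, SE 0.254), were among them. The score was 0.55 higher with no overlap (exact permutation test, two-sided p = 0.1, the smallest possible). Lower in Samhd1 Cardif dKO were Aldh1a3 (-6.83), Dbp (-2.64), Gimap4 (-2.23), Igh-6 (-2.10), Cd22 (-2.03) and Mavs (-0.80). B cell markers were lower in 3 of 21 cases (18 by DESeq2, 20 adjusted over the list alone, median -1.96, camera adjusted p = 3.83e-21, and adjusted p = 0.235 with an estimated correlation). Cell cycle genes had a median of 2.43, with 0 of 37 called by limma or edgeR, 37 higher at an unadjusted p under 0.05, 15 by DESeq2 and 37 adjusted over the list alone (camera adjusted p = 1.07e-22, and adjusted p = 0.259 with an estimated correlation). Limma called 12 genes higher and 25 lower. In the authors' deposited table of the same comparison, 112 genes were higher and 43 lower in the libraries labelled Samhd1 Sting dKO at an adjusted p under 0.1. Of the 37 genes called here at 0.05, 36 were among them, all 36 in the same direction. At an adjusted p under 0.05 the authors' table held 94 genes. Both tests read the same dKO libraries, so the shared direction is not independent evidence. The count of 37 became 17 and 1 without WT replicate 1 or 3, 22 without Samhd1 KO replicate 3, 8, 14 and 2 without Samhd1 Cardif dKO replicate 1, 2 or 3, and 12, 9 and 13 without Samhd1 Sting dKO replicate 1, 2 or 3. The 9 interferon genes became 4 and 0 without WT replicate 1 or 3, 4 without Samhd1 KO replicate 3, 4, 0 and 0 without Samhd1 Cardif dKO replicate 1, 2 or 3, and 0, 1 and 1 without Samhd1 Sting dKO replicate 1, 2 or 3. The 9 also became 3 by voom, 2 from the 2 groups alone, 4 with sex, 0 with age or the B cell score and 5 with the cell cycle score as a covariate, and 26 by DESeq2. The count of 37 was 7 from the 2 groups alone, 8 with sex, 4 with age, 7 with the cell cycle score and 1 with the B cell score as a covariate, and 482 by DESeq2.

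**Figure D3:**
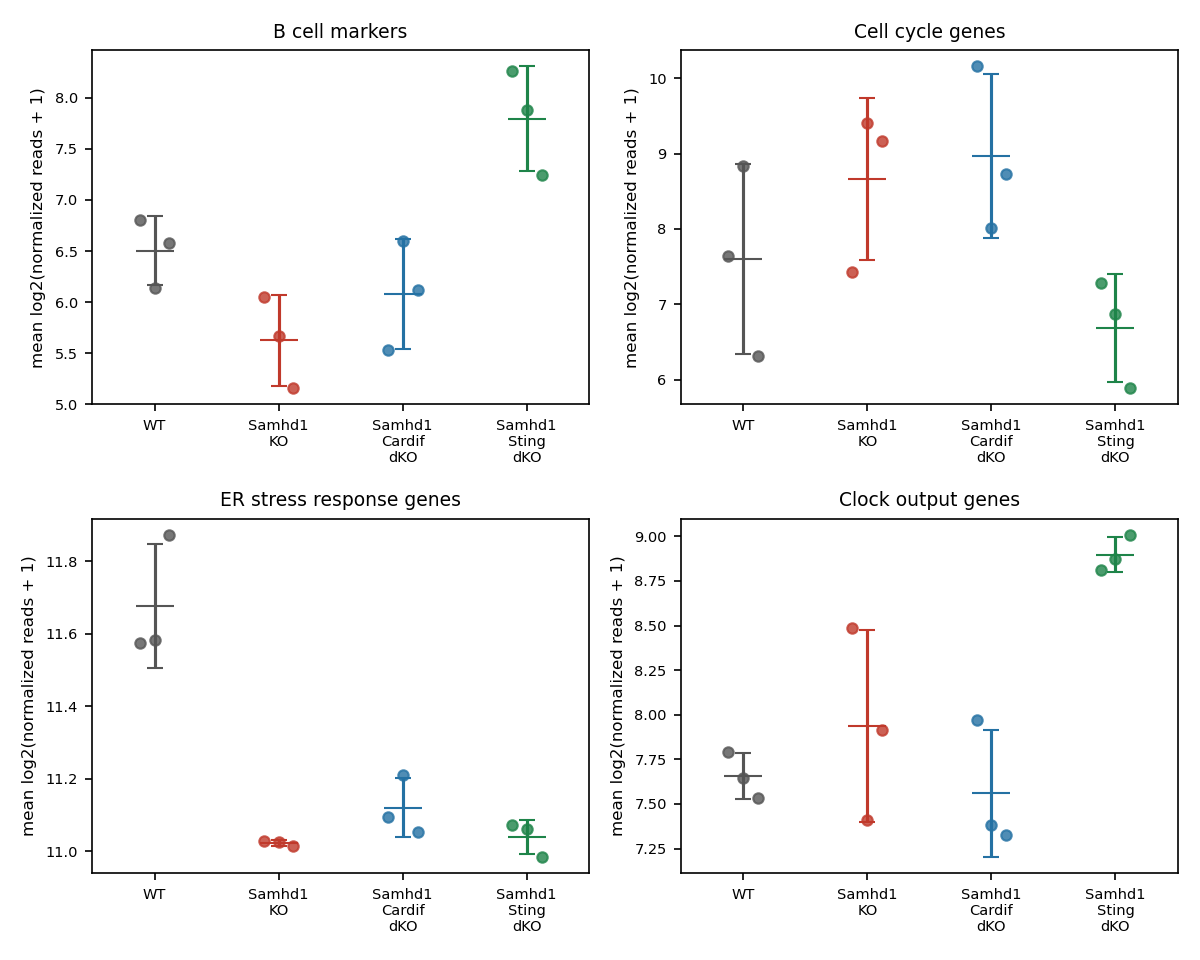
Mean of log2(normalized reads + 1) over the tested genes of 4 lists for each library (points), with the mean and SD of 3 libraries per group (bars and whiskers); the axes do not start at 0, and the ER stress and clock output lists were chosen after the values were seen. The B cell score was 7.80 in Samhd1 Sting dKO, 6.50 in WT, 6.08 in Samhd1 Cardif dKO and 5.63 in Samhd1 KO, and the cell cycle score was 6.68, 7.60, 8.97 and 8.66 in the same order.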

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

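The splits of the samples were planned, and the tests on B cells, macrophage share and time of day were chosen after the results were seen. Their bounds were set or changed after the values were known; under the bound first written, an r below 0, the test of the clock score against the B cell score would have counted against B cells. That relation was tested in 3 forms, all printed below.

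The direct test of both dKO groups flagged 37 genes as differing between them. The groups also differed in B cell markers and, by their labels, in age and sex. Their cell cycle scores differed too, at 8.97 ± 1.09 in Samhd1 Cardif dKO and 6.68 ± 0.719 in Samhd1 Sting dKO, with no overlap. An effect of the second knockout was not told apart from these. The log2 difference, Samhd1 Cardif dKO minus the libraries labelled Samhd1 Sting dKO, was 2.13 for Oasl1, 1.61 for Ifi27l2b, 1.59 for Ifi27l2a, 1.44 for Oas3 and 1.43 for Usp18. It was -6.83 for Aldh1a3, -2.64 for Dbp, -2.23 for Gimap4, -2.10 for Igh-6, -2.03 for Cd22 and -0.80 for Mavs. List medians flagged by the same test were 0.40 for type I interferon response genes, 0.19 for MHC class I, -0.64 for MHC class II, 0.38 for deoxynucleotide metabolism, 2.43 for cell cycle genes, -1.96 for B cell markers, -1.10 for T and NK cell markers and -1.75 for mast cell, eosinophil and basophil markers. None of these lists passed with an estimated correlation. Groups of 3 were not tested for single libraries that stand apart.

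B cell markers were higher in the libraries labelled Samhd1 Sting dKO than in Samhd1 KO (median log2 2.47), although the cells had been sorted by FACS for macrophages. If B cells or their RNA were carried into the samples, the list's members should move together between libraries of a group: its 2 parts, each centred on its group means, correlated with r = 0.974 over 12 libraries (Spearman 0.923; 1296 within-group permutations, p = 0.000772 and 0.00154, adjusted over 2 relations 0.00154 and 0.00309; 0.966 without the 2 farthest libraries). Igh-6 went from 327 to 1964, Cd79b from 79.4 to 502 and Cd22 from 63.0 to 398 normalized reads, with 14 of the 21 tested members at 50 or more in every WT library and 0 on another list. Mast cell, eosinophil and basophil markers (median 2.35, 5 of 10 called by limma) and T and NK cell markers (1.22, 0 of 6) also had positive medians (camera adjusted p = 0.135 and 0.0980 with an estimated correlation). A lower share of macrophages would raise every other cell type alike. The B cell median exceeded that of small macrophage, monocyte and dendritic cell markers by 2.46 (95% bootstrap interval 1.99 to 2.85). Over members no higher in WT than the upper quartile of the B cell list it did so by 2.51 (2.00 to 3.12). The difference was 2.53 (1.97 to 3.16) for neutrophil markers and 0.116 (-1.59 to 2.57) for mast cell, eosinophil and basophil markers. These intervals resample the genes of the lists, not animals. Small macrophage, monocyte and dendritic cell markers were already higher in Samhd1 KO than in WT (median 0.67). Against WT, score differences in these libraries were 1.29 for B cell markers and 0.67 for T and NK cell markers. They were 0.47 for the small macrophage list, 0.42 for the mast cell list, 0.23 for neutrophil and -0.07 for red cell and platelet markers. As list medians against Samhd1 KO, the values go against an equal rise of every other cell type. Mast cell markers did not separate from B cell markers. With that baseline already shifted, the values cannot decide on a lower share of macrophages. The correlation of the 2 parts cannot tell carried-over B cells from another cause that moves these genes together. B cells in the sort may account for the marker genes, while a difference between the animals in age (16 to 24 in this group) or genotype in how many B cells were present stays open and untested.

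Clock output genes such as Dbp, Nr1d1 and Tef were also higher in the libraries labelled Samhd1 Sting dKO than in Samhd1 KO (median 0.72, 3 of 9 called). Sampling at another time of day could give this, and then genes of the opposite phase should be lower. Their median was -0.44 (interval -1.49 to 0.0838, 4 genes). Cry1 (-1.49, adjusted p = 0.0133) and Nfil3 (-0.80, adjusted p = 0.00365) were lower, while Clock was at -0.08 and Arntl at 0.08. With 4 genes the interval runs from the lowest to the highest gene, so it cannot decide, and time of day stays open. B cells as the source would tie the clock score to the B cell score, but r was -0.138 over 12 libraries (interval -0.706 to 0.538, Spearman -0.224, permutation p = 0.705 and 0.562, adjusted 0.705 and 0.562; 0.209 without the 2 farthest libraries), too wide to decide. The slope within groups was -0.124 on normalized reads over their mean (interval -0.513 to 0.265), below the 0.469 needed for the whole difference, but this rests on 1 library (-0.0687, -0.871 to 0.734, needed 0.351 without Samhd1 Sting dKO replicate 3), and on log2 scores the interval held the needed 0.442 (-0.0988, -0.733 to 0.535), so B cells stay open. An effect of genotype was not tested.

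Other splits of the same 6 libraries were counted for each comparison. In every one, 1 of 10 splits, the real one, gave as many genes. The real split gave 572, 19, 749, 140, 860 and 37 genes in the order of the comparisons above, and the highest of the others gave 0, 0, 0, 0, 1 and 0. With 10 splits a share under 0.05 cannot be reached.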

How the results depend on the processing

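Covariates for the B cell and cell cycle scores and the use of TMM on the recovered reads were chosen after the data were seen. Counts of all genes, of interferon genes and of the split that are neither printed nor inside a printed range stayed within 1.5 times the value reported. Counts of the other lists were repeated only by edgeR with TMM and by DESeq2, and some moved by more. Where fewer libraries were used, fewer residual degrees of freedom are part of the reason; otherwise the cause was not tested. The order of comparisons is Samhd1 KO against WT, Samhd1 Cardif dKO against Samhd1 KO, Samhd1 Sting dKO against Samhd1 KO, Samhd1 Cardif dKO against WT, Samhd1 Sting dKO against WT, and Samhd1 Cardif dKO against Samhd1 Sting dKO. At an adjusted p of 0.10 the counts were 1037, 46, 1395, 303, 1560 and 126, and DESeq2 gave 1056, 186, 1284, 475, 1391 and 482. Interferon genes by DESeq2 were 47 lower in the second, 3 higher in the fourth, 21 lower in the fifth and 26 higher in the sixth. A filter at 5 CPM gave 11 genes (3 interferon genes) in the second. The 2 groups alone gave 1 gene (0 interferon) in the second, 461 in the third, 67 in the fourth and 7 (2 interferon) in the sixth. Sex as a covariate gave 0 (0 interferon), 42 and 8 (4 interferon) in the second, the fourth and the sixth. Age gave 6 (1 interferon), 423 (6 interferon) and 4 (0 interferon) in the second, the fifth and the sixth. TMM factors gave 3 interferon genes in the second, and limma-voom 3 in the sixth. The B cell score gave 124, 49 (25 interferon), 33 (21 interferon), 48, 140 (8 interferon) and 1 (0 interferon), and the cell cycle score 66 (27 interferon) in the second, 241 in the third, 59 in the fourth, 24 interferon genes in the fifth and 7 (5 interferon) in the sixth. Because the B cell score differs between groups, this covariate also removes group differences: Ly6d (-0.0578), Igk-C (-0.12), Cd79a (-0.10), Igl-C2 (-0.52), H2-DMb2 (-0.20) and Il5ra (-0.87) reversed with it in Samhd1 Sting dKO against Samhd1 KO.

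Replicate numbers did not pair the samples: correlations between libraries of the same number ran from -0.427 to 0.369 and those of other pairs from -0.470 to 0.537, and 3 of 12 libraries correlated best with their own number. With a replicate block the counts were 2 (0 interferon) in the second comparison and 23 (1 interferon) in the sixth, 8 interferon genes in the fifth, and 1 gene in the split for Samhd1 Cardif dKO, which has no bearing on the strength of an effect.

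Of the genes higher in Samhd1 KO, those called lower in Samhd1 Cardif dKO were 9 with the 5 CPM filter, 134 by DESeq2, 1 with the 2 groups alone, 0 with sex, 4 with age, 43 with the B cell score, 52 with the cell cycle score and 334 by sign alone. Those called lower in Samhd1 Sting dKO were 242 by DESeq2, 100 with age, 31 with the B cell score and 295 by sign alone. Lists passing camera fell from 10, 11, 10, 5, 7 and 8 to 0, 2, 0, 0, 0 and 0 with an estimated correlation. The score difference moved to -0.52 and -1.06 in the second and the third comparison when the median of genes replaced the mean. Samhd1 in Samhd1 KO against WT was no longer called with age (log2 -0.70), the B cell score (-0.72) or the cell cycle score (-0.65). Mavs in Samhd1 Cardif dKO against Samhd1 KO was not called with the 2 groups alone (-0.81) or sex (-0.80), nor Tmem173 in Samhd1 Sting dKO against Samhd1 KO with the 2 groups alone (-0.41), the B cell score (-0.56) or the cell cycle score (-0.45).

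Leaving out each library in turn gave 185 to 610, 0 to 31, 421 to 864, 37 to 160, 358 to 904 and 1 to 44 genes, with 27 to 59, 0 to 15, 61 to 70, 0 to 1, 7 to 21 and 0 to 12 interferon genes. The split ran from 0 to 25 genes for Samhd1 Cardif dKO and from 59 to 174 for Samhd1 Sting dKO. The score differences ran from 0.76 to 1.00, -0.86 to -0.63, -1.36 to -1.26, 0.00370 to 0.26, -0.55 to -0.31 and 0.45 to 0.68, and no sign changed. Samhd1 ran from -0.87 to -0.63, Mavs from -0.87 to -0.77 and Tmem173 from -0.45 to -0.38. Of the named called genes, 21 of 59, 0 of 12, 9 of 61, 4 of 12, 5 of 11 and 1 of 11 kept their call and direction in each of the 27 settings that gave a value. No alternative of the plan was left out, and depth limits calls among genes with few reads.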

Other observations

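The ER stress list and the test of heat shock and ER genes were chosen after the values were seen, so these lists are not independent evidence of their direction, and no enrichment test was run on them. Of 32 ER stress response genes, 22, 12 and 22 were called lower than WT in Samhd1 KO, Samhd1 Cardif dKO and the libraries labelled Samhd1 Sting dKO, and of 9 heat shock genes 6, 6 and 6. Hspa5, the main ER chaperone, was at 42266 ± 7263 normalized reads in WT, 20057 ± 1012 in Samhd1 KO, 23871 ± 3564 in Samhd1 Cardif dKO and 17670 ± 2011 in the libraries labelled Samhd1 Sting dKO (log2 -1.06, -0.82 and -1.25 against WT). Herpud1 was at log2 -1.25, -1.23 and -1.32, and Dnajb9, Manf and Hyou1 were at -1.27, -1.30 and -1.24 in Samhd1 KO. Over all genes, 57 were lower than WT in all 3 groups and 34 higher, where independent lists would give 0.0446 and 0.0444 and simulations with all groups alike gave 0. The first leaves out the shared WT libraries and the second has almost no calls, so neither tests the overlap, and how much of it came from the shared libraries is not known.

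Stress of the WT samples during isolation would raise immediate early genes in WT as well. Their median over the 3 deficient groups was 0.32 (95% bootstrap interval -0.0413 to 0.563), above that of the heat shock and ER genes (-0.58). That interval includes 0, and the genes compared were chosen after their values were seen. Of 17 immediate early genes, 3, 8 and 7 had a negative and 14, 9 and 10 a positive change against WT. The order is Samhd1 KO, Samhd1 Cardif dKO and the libraries labelled Samhd1 Sting dKO. Stress during isolation thus stays open. In Samhd1 Cardif dKO, where the interferon list was near the WT level, the heat shock and ER genes stayed low (median -0.53, interval -0.746 to -0.379, against -0.56 in Samhd1 KO). These genes were picked for being low in all 3 groups, which are compared with the same WT libraries. This therefore cannot decide whether the interferon response was the source. A day or batch shared by the WT samples cannot be separated from genotype, as the labels give neither, and loss of SAMHD1 itself was not tested further.

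Ptprd, singled out after its values were seen, was at 76.0 ± 35.9 in WT, listed at 0 in all 3 Samhd1 KO libraries, and at 0.341 ± 0.591 and 0.375 ± 0.650 in the dKO groups.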
